A study of Mus musculus with 6 samples.

How the data were processed

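Total RNA of 6 cultures was hybridised to Affymetrix Mouse Gene 2.0 ST arrays, 1 array for each combination of 2 cell states (mESC of the EB3 line and EpiLC made from them) and 3 treatments (none, CHIR, CHIR with PD). Media, doses and times are those of the labels' protocols, and RNA isolation with RNeasy columns, the WT PLUS labelling kit and GeneSpring GX 11.5 are named per the series' design text. The deposited value of each transcript cluster is a linear intensity, normalized between arrays by the authors with a method not given in the sources used here. The lowest intensity was 16 on every array and the distributions of the arrays were nearly but not exactly equal, as tested on the table. Differences of genes close to this lowest value are compressed. Raw array files were not used here, and no genome build is given in the sources used here, so genes are named by symbol without positions.

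The table held 33793 probes with 0 missing values. Of these, 23521 carried 1 gene symbol, 1814 carried several and 8458 were not listed with a gene. Probes with 1 symbol were used, and log2 intensities were averaged per symbol, which gave 22180 genes, 1082 of them with more than 1 probe. The Entrez identifiers of 23328 probes were found in the gene name table, and 0 symbols changed. Probes with several symbols or none were left out of the comparisons because their signal cannot be assigned to 1 gene. No filter on dim genes and no further scaling was applied.

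Choices of tests, lists, thresholds and most alternatives were fixed before the data were examined. One linear model of cell state plus treatment, without interaction, was fitted to the 6 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default moderation), and gave 4 comparisons, namely EpiLC against mESC, CHIR against untreated, CHIR with PD against CHIR, and CHIR with PD against untreated. Its residual is the departure from additive effects, so a gene whose response differs between the states gets a large error. Adjusted p-values are Benjamini-Hochberg values over all genes of a comparison, with a threshold of 0.05, two-sided. Another 7 comparisons set 1 array against 1 array and give sizes only, counting genes that differ at least 2-fold. EpiLC were also set against mESC within each of the 2 inhibitor treatments, for values only. The spread on the log2 scale is that of the model where an SE is given.

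The 22 gene lists covered core, naive and formative pluripotency, primitive streak and mesendoderm, Wnt/beta-catenin targets, ERK-dependent genes, Activin/Nodal, BMP and LIF-STAT3 targets, primitive endoderm, neuroectoderm, trophoblast, 2-cell-like and germline genes, DNA methylation machinery, glycolysis, cell cycle, p53 targets, cholesterol synthesis, amino acid and ER stress, fibroblast (feeder) markers and ribosomal proteins. They hold 227 distinct genes, of which 210 were measured by a probe with 1 symbol and 17 were not, among them T and Tcf7. A list's median log2 difference was placed among 10000 random lists of the same size matched on mean expression (a window of 200 genes), and a list outside the 2.5 to 97.5 percentiles was said to stand apart. Random genes are not regulated together as list members may be, so a percentile describes a list and is no p-value. For the 4 fitted comparisons members were also adjusted over the list alone. Another 8 lists were written after a first look at the values (interferon-stimulated genes, NF-kB targets, retinoic acid targets, visceral endoderm, paraxial and presomitic mesoderm, endothelial and blood, caudal epiblast Hox and Cdx genes, anterior neural genes).

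Genes were named by a rule. For each comparison it takes the 10 genes with the largest positive and the 10 with the largest negative difference, among genes past the threshold in the fitted comparisons, and up to 4 members of each list with the largest absolute difference. Predicted, clone and small RNA symbols are passed over, and a gene may be named again elsewhere to set its values side by side. Responses of the 2 states were compared by Pearson and Spearman correlation across genes and by the overlap of genes differing at least 2-fold. Overlaps of comparisons that share the untreated array were set against 100 simulations of arrays without effects (seed 20240), whose spread includes departures between the states and so overstates the noise.

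The fit was tested on simulated data with 200 changed genes in 10 simulations. For EpiLC against mESC it recovered 68.3% of 2-fold and 97.7% of 4-fold changes, with 4.9% false calls. For CHIR, for PD added to CHIR and for CHIR with PD it recovered 23.2%, 26.7% and 27.9% of 2-fold and 93.4%, 94.1% and 94% of 4-fold changes, with 4.1%, 4.9% and 4.9% false calls. Simulated changes were the same in both states, and errors were drawn from the spread that the fit assumes. Recovery is thus not shown for genes whose response differs between the states. Recovery also depends on how many genes change, because the adjustment runs over all genes. A lack of genes past the threshold for CHIR does not show that 4-fold changes are absent. Mixl1, at a log2 difference of 3.76 (SE 0.27) for CHIR over both states, did not pass it. Of 200 simulated lists of 12 genes, 5.5% stood apart without a shift and 100% with a shift of 0.5 on the log2 scale. These lists held random genes, so their share does not cover lists whose members move together. Alternatives were the probe with the highest mean, quantile normalization again, centring each array on its median, genes above the median level, every probe as its own feature, limma with trend and robust moderation, no moderation, no treatment block, leaving out each treatment's pair of arrays, a threshold of 1.5-fold, and unmatched random lists. Constants of 4 and 64 in place of 16 were added after the lowest intensity had been seen. Tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots with matplotlib 3.10.9.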

Results

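Gene expression was measured in EB3 cells, a line of mouse embryonic stem cells (mESC), and in epiblast-like cells (EpiLC), a state close to the early post-implantation epiblast. EpiLC had been induced from the stem cells over 2 days with 20 ng/ml Activin A and 12 ng/ml bFGF, whereas the stem cells were kept with LIF and BMP4, per the labels. Each state was left untreated, treated for 24 hours with 3 µM CHIR99021 (CHIR, an inhibitor of the kinase GSK3 that stabilises beta-catenin), or treated for 24 hours with 3 µM CHIR and 1 µM PD0325901 (PD, an inhibitor of MEK, the kinase that activates ERK1/2). PD was given only together with CHIR, and the labels used here do not say how the 24 hours lay relative to the induction. Each of the 6 groups was 1 array, so there were no replicates, single-array differences have no error and no p-value, and the number of arrays limits the precision of every value. The series title names Activin A and inhibition of the ERK1/2 pathway in stem cell propagation as its subject, and the design sets the response of Activin A-treated EpiLC beside that of mESC. Median intensity over all probes lay between 60.55 and 65.17 on the 6 arrays. The arrays of untreated and CHIR-treated mESC were the closest pair (Pearson r = 0.99 across genes, which are not independent replicates).

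Naive pluripotency genes, which mark the pre-implantation epiblast, were low in EpiLC. All 16 naive genes measured were at least 2-fold lower in untreated EpiLC than in untreated mESC, with a median log2 difference of -3.53, and 15 of the 16 fell over the 3 treatments in the limma fit, all but Gbx2. That gene, an average of 2 probes, was at -1.14 in the untreated pair and at -0.10 on its brighter probe. The values that follow for single genes are log2 differences over the 3 treatments with 3 arrays per state, and each named gene that rose or fell did so in all 3 pairs of arrays. Nr0b1 fell by 5.17 on the log2 scale (SE 0.28, limma adjusted p = 0.00161), Tbx3 fell by 4.29 (SE 0.20, limma adjusted p = 0.000889) and Tfcp2l1 fell by 4.22 (SE 0.21, limma adjusted p = 0.00116). The orphan nuclear receptor Esrrb was at an intensity of 357 in untreated mESC and 22.5 in untreated EpiLC. Targets of BMP and LIF, which were in the stem cell medium, were lower as well, and 3 of 6 BMP targets and 4 of 7 LIF-STAT3 targets fell (medians -1.95 and -0.94 in the untreated pair). Id1, an inhibitor of differentiation induced by BMP, went from 1480.2 in untreated mESC to 57.3 in untreated EpiLC, and Bcl3 fell by 3.87 (SE 0.29).

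Formative epiblast genes took the opposite direction. Of 12 genes of that list, 9 were at least 2-fold higher in untreated EpiLC (median log2 difference 1.20), and 6 rose over the 3 treatments. Fgf5, the classical marker of the post-implantation epiblast, was at 36.0 in untreated mESC and 1258.5 in untreated EpiLC. Over the 3 treatments its difference of 3.52 (SE 0.77) missed the limma threshold (adjusted p = 0.0506). Cdh2, which encodes N-cadherin, rose by 1.76 (SE 0.34), and Wnt8a rose by 2.25 (SE 0.39). Among 7 Activin/Nodal targets 2 rose, namely Lefty2 (adjusted p = 0.00474 in limma) and Nodal, which rose by 0.98 (SE 0.16), and Lefty1 was at 79.2 and 407.5 in the untreated states. Mixl1 and Fgf8, genes of the primitive streak, rose by 2.73 (SE 0.22) and 2.97 (SE 0.46), and Eomes went from 55.5 to 345 in the untreated pair. Outside the lists, Apln, which encodes the ligand apelin, rose by 4.24 (SE 0.48), the Activin antagonist Fst rose by 3.30 (SE 0.31), and the cell adhesion gene Jam2 fell by 5.02 (SE 0.10).

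Core pluripotency genes differed less between the untreated states than naive genes did. Their median log2 difference was -0.32, Nanog was at 2118 in mESC and 709 in EpiLC, and Sox2 was at 1514 and 599. Pou5f1, named after its values had been seen, was at 1342 and 1289.5. Over the 3 treatments 4 of 12 core genes fell, among them Sox2 (adjusted p = 0.026 in limma) and Gdf3, which fell by 2.21 (SE 0.44). In the DNA methylation list Dnmt3l fell by 2.65 (SE 0.39), Tet2 fell by 2.90 (SE 0.22), Tet1 fell by 1.81 (SE 0.26) and Dnmt3a rose by 0.97 (SE 0.15). The trophoblast list was lower in untreated EpiLC (median -1.01), and over the 3 treatments 3 of its 8 members fell, including Tfap2c, which fell by 3.40 (SE 0.13), and Hand1, which fell by 2.80 (SE 0.13). Fibroblast markers, fixed to look for feeder cells, were higher in untreated EpiLC by a median of 0.22 (percentile 98.2 of random lists), led by Col1a1 (84.3 and 198) and Acta2 (316.5 and 613).

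In the limma fit of state and treatment over all 6 arrays, 921 of 22180 genes rose and 920 fell in EpiLC. In the untreated pair, 325 genes were at least 2-fold higher and 510 at least 2-fold lower, 447 in all with a constant of 64 in place of 16 in the intensities. Adjusted over the list alone, 7 core, 15 naive, 4 BMP, 5 LIF-STAT3, 4 DNA methylation and 3 trophoblast genes fell, and 11 formative, 6 streak and 5 Activin/Nodal genes rose. Of 22 lists 13 stood apart from random lists of like expression over the 3 treatments, where about 1.1 would if list members varied independently. Members that are regulated together move together with any difference between cultures, so 1.1 is not the number that chance would give. The spread in this fit is the departure from additive effects over 2 residual degrees of freedom, and the count became 945 without the CHIR pair of arrays, 1209 without the pair with CHIR and PD, and 0 without moderation of the variances.

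**Figure D1:**
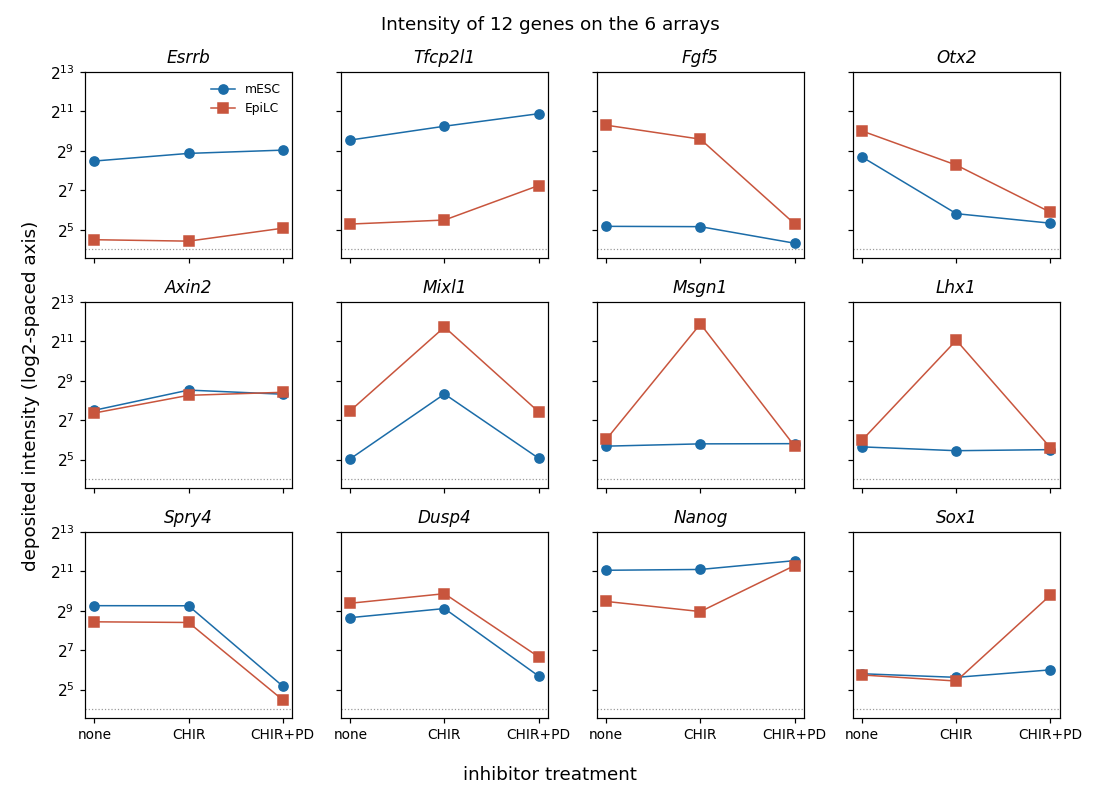
Intensity of 12 genes on the 6 arrays, on a log2-spaced vertical axis, by treatment (none, CHIR, CHIR with PD), with circles for mESC, squares for EpiLC and a dotted line at the lowest deposited intensity of 16. Each point is 1 array and lines only join arrays of one state; Msgn1 stands at 3768 on the EpiLC array with CHIR and at 51.7 on that with CHIR and PD.

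In mESC, CHIR was followed by higher Wnt target genes and lower formative genes. Of 13 Wnt/beta-catenin targets, 4 were at least 2-fold higher (median log2 difference 0.54, percentile 100 of random lists), with Sp5 higher by 1.78, Dkk1 higher by 1.52 and Axin2, a negative-feedback gene of the pathway, higher by 1.02. Mixl1 went from 33.0 to 321 and Cdx1, a caudal homeobox gene, from 28.6 to 258, although the streak and mesendoderm list that holds both did not stand apart (median 0.08, percentile 90.3, 3 of 14 at least 2-fold higher). Otx2, a transcription factor of the anterior epiblast, went from 410.5 to 56.2, and Dnmt3b was lower by 0.85. The formative list had a median of -0.42 (percentile 0), whereas the naive list had a median of 0.04 (percentile 76.3), with Tfcp2l1 higher by 0.70 and Tbx3 higher by 0.78. Spic, which encodes a transcription factor of the Ets family, had the lowest value of the comparison, going from 785 to 91.5. Core pluripotency genes were lower (median -0.22, percentile 0.01, 11 of 12 lower and 0 at least 2-fold lower). Activin/Nodal targets stood apart with a median of 0.44 (percentile 99.99), 4 being higher and 3 lower. The ERK-dependent list had a median of -0.01, and the cell cycle inhibitor Cdkn1a was higher by 1.07. In all, 41 genes were at least 2-fold higher and 34 lower.

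In EpiLC, CHIR was followed by high levels of streak and mesendoderm genes. Of 14 primitive streak and mesendoderm genes, 10 were at least 2-fold higher and 0 lower (median 2.17, percentile 100). Msgn1, which encodes a transcription factor of the presomitic mesoderm, went from 65.2 to 3768, Lhx1 from 63.7 to 2121, Tbx6 from 52.5 to 816 and Mixl1 from 179 to 3378. The apelin receptor gene Aplnr went from 33.7, under the lower quartile of 34.5 on that array, to 4485. Hoxb1 was higher by 5.54, Hoxb2 went from 34.4 to 1102, and Cyp26a1, which encodes an enzyme that degrades retinoic acid, went from 29.7 to 917. Wnt targets had a median of 0.90 (percentile 100), with Dkk1 higher by 3.65, Sp5 by 2.90 and Nkd1 by 2.20. The primitive endoderm list had a median of 0.58 (percentile 100), led by Pdgfra (18.0 to 224) and Gata6 (85.9 to 619), which mesoderm also expresses. The stress-response gene Ddit4 went from 314 to 2255, and the amino acid and ER stress list had a median of 0.42 (percentile 99.9).

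Pluripotency genes were lower in the same EpiLC culture. Of 12 core genes, 6 were at least 2-fold lower and 0 higher (median -1.03, percentile 0), with Sox2 going from 599 to 106, Utf1, a chromatin-associated factor, from 3091.5 to 473, Gdf3 from 440.0 to 72.0 and Dppa2 from 1239 to 216. Of 12 formative genes 7 were at least 2-fold lower (median -1.17), including Pou3f1 by -2.13 and Dnmt3b by -1.92, while Cdh2 was higher by 2.62. The growth factor gene Fgf4 was lower by -3.24. The germline list had a median of -0.83, with Mael at -1.70 and Dazl at -1.66, and the DNA methylation list a median of -0.73. Activin/Nodal targets had a median of -0.60 (percentile 0.02), with Smad7 at -2.56 and Lefty1 at -0.76 but Lefty2 at 1.25. The ERK-dependent list had a median of 0.08 (percentile 77.6) and the naive list one of 0.00 (percentile 42.2). In all, 392 genes were at least 2-fold higher and 206 lower.

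Over both states together, no gene passed the limma threshold for CHIR (smallest adjusted p = 0.28, 0 of 22180 genes, 1613 at an unadjusted p under 0.05). Without any effect, a share of about 0.05 of the genes would have such an unadjusted p. Adjusted over the list alone, 6 of 13 Wnt targets rose, among them Tnfrsf19 by 1.19 (SE 0.16), Axin2 by 0.96 (SE 0.14) and Sp5 by 2.34 (SE 0.40). Likewise adjusted over the list alone, 4 of 14 streak genes rose, led by Mixl1 (3.76, SE 0.27), and 7 of 12 formative genes fell, led by Otx2 (-2.30, SE 0.42), while Cdh2 rose. This fit has 2 arrays per treatment, and a gene that responds in one state alone gets a large residual in it.

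When PD was added to CHIR, feedback genes of ERK signalling fell over the 2 states. In all 4 genes fell past the limma threshold over all genes, namely Spry4 (log2 difference -3.99, SE 0.12, adjusted p = 0.0025), Dusp4 (-3.31, SE 0.13, adjusted p = 0.00522), Etv4 (-3.28, SE 0.19, adjusted p = 0.0205) and Dusp6 (-2.36, SE 0.13, adjusted p = 0.0205), the last an average of 2 probes, each of the 4 lower in both states. Spry4 and the dual-specificity phosphatases Dusp4 and Dusp6 dampen receptor and ERK signalling, and Etv4 is a transcription factor induced by it. 0 genes rose, and 1280 of 22180 genes had an unadjusted p under 0.05, where a share of about 0.05 would without any effect. Of 19 ERK-dependent genes, 4 fell over all genes and 15 fell adjusted over the list alone, and 10 were at least 2-fold lower in each state (medians -1.33 in mESC and -1.08 in EpiLC). Adjusted over the list alone, Mixl1 fell by 3.78 (SE 0.27), while Krt7, Krt8, Krt18 and Hand1 of the trophoblast list rose. The limma count of 4 became 7 with trend and robust moderation, 3 with a constant of 4 in place of 16 (of which 2, Spry4 and Dusp4, were among the 4), 1 with a constant of 64 in place of 16 in the intensities, and 0 without moderation.

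In mESC, addition of PD to CHIR was followed by lower formative, streak and core pluripotency genes and higher trophoblast genes. The formative list had a median of -0.46 (percentile 0.01, 10 of 12 lower) and the core list one of -0.32 (percentile 0, 2 of 12 at least 2-fold lower). The trophoblast list had a median of 0.61 (percentile 100), with 7 of 8 genes higher, 2 of them at least 2-fold, and 1 at least 2-fold lower. Mixl1 went from 321 back to 33.6, Cdx1 was lower by -1.22, and the streak list had a median of -0.36 (percentile 0). Utf1 went from 2021 to 287, Dnmt3l from 483.5 to 119.5 and Bmp4 from 1670.2 to 200.2. BMP targets had a median of -0.27 (percentile 1.98), with Id1 at -1.31 and Id3 at -1.15. The Ets factor gene Spic went from 91.5 to 1638, and S100a13 and Calcoco2 were higher by 3.07 and 3.11. The naive list had a median of 0.17 (percentile 99.7), with Prdm14 higher by 0.93 and Tfcp2l1 by 0.63, and the keratin genes Krt8 and Krt18 were higher by 1.01 and 1.06. In all, 56 genes were at least 2-fold higher and 116 lower, with totals of 425 and 73 for constants of 4 and 64 in place of 16.

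In EpiLC, addition of PD to CHIR was followed by low levels of the mesoderm genes. Msgn1 went from 3768 to 51.7, Lhx1 from 2121 to 48.6, Tbx6 from 816 to 61.3, Mixl1 from 3378 to 172 and Cyp26a1 from 917 to 29.9, and 8 of 14 streak genes were at least 2-fold lower (median -2.02). Fgf5 went from 770.0 to 39.4, Tdgf1, which encodes a Nodal co-receptor, from 2354 to 156, and Otx2 was lower by -2.39. The formative list, which holds Fgf5 and Otx2, did not stand apart, with 6 of 12 genes higher and 6 lower (median 0.06, percentile 76.9). Nanog went from 496 to 2498.5, Klf2 from 67.4 to 307, Tfcp2l1 from 44.9 to 151 and Sox2 from 106 to 302, and Lefty1, an inhibitor of Nodal signalling, from 240.4 to 3548. The core list went both ways, with 5 of 12 genes higher and 7 lower (median -0.64, percentile 0), Nanog and Sox2 being the 2 that were at least 2-fold higher. All 7 Activin/Nodal targets were higher (median 0.63, percentile 99.99). Sox1, an early neural transcription factor gene, went from 43.2 to 885. The neuroectoderm list had a median of 0.26 (percentile 99.4), but 5 of 9 genes were higher and 4 lower, and only 1, Sox1, was at least 2-fold higher. Against untreated EpiLC that list had a median of -0.20 with CHIR and PD (percentile 8.29). Stra6 (62.2 to 1356), Wnt6 (81.1 to 1396) and the chemokine genes Cxcl11 (36.7 to 1055) and Cxcl10 (57.5 to 870) were also among the highest. Fibroblast markers had a median of 0.27 (percentile 99.6), led by Acta2 (1.74) and Col1a1 (1.17). In all, 230 genes were at least 2-fold higher and 225 lower, with totals of 894 and 255 for constants of 4 and 64.

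**Figure D2:**
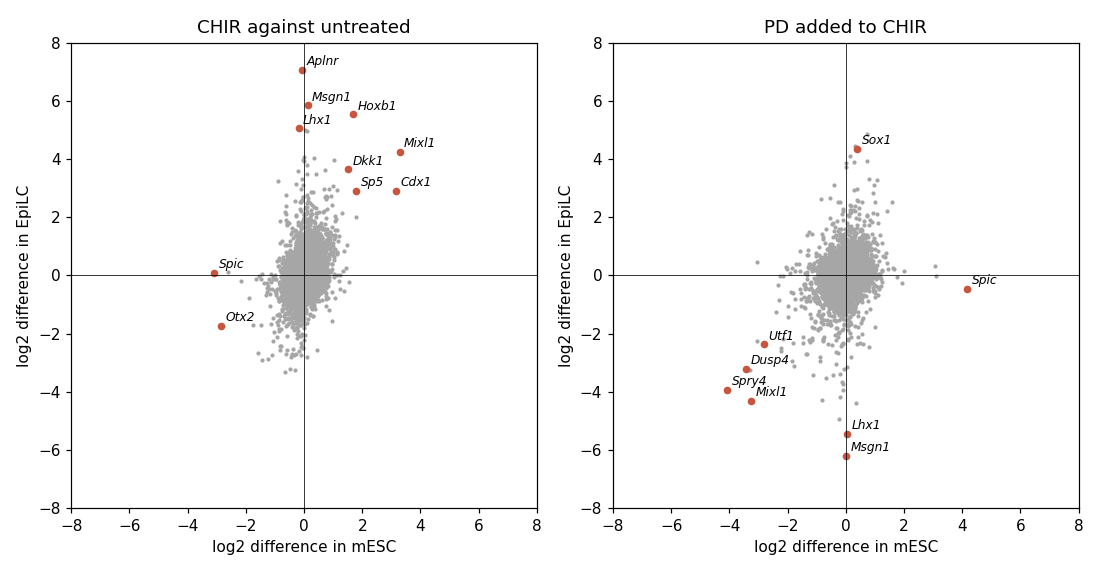
Log2 difference of each of 22180 genes in mESC (horizontal) and EpiLC (vertical), for CHIR against untreated on the left and for PD added to CHIR on the right, each difference from 1 array against 1 array. Named genes are drawn larger; Msgn1 lies near 0 in mESC and at 5.85 and -6.19 in EpiLC, and Spry4 lies at -4.07 and -3.92.

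Set against untreated cells, CHIR with PD in mESC gave lower ERK-dependent and formative genes and higher Wnt target genes. The ERK list had a median of -1.25, and Spry4 was at -4.07. Otx2 went from 410.5 to 40.2, Dnmt3b was at -1.51, and the formative list had a median of -0.73 (percentile 0). Wnt targets had a median of 0.62 (percentile 100), with Dkk1 at 2.33 and Sp5 at 1.66, although Lef1 was at -1.45. The naive list was higher by a median of 0.22 (percentile 99.5), with Tfcp2l1 going from 747 to 1884 and Tbx3 higher by 1.02. Aqp3, which encodes a water and glycerol channel, went from 496 to 2738, and Enpp3 went from 1242 to 87.6. In all, 137 genes were at least 2-fold higher and 188 lower, with totals of 681 and 157 for constants of 4 and 64.

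In EpiLC, the same combination left most naive genes at low levels. Against mESC under CHIR and PD, 15 of 16 naive genes were at least 2-fold lower (median -3.36), with Esrrb at 524 in mESC and 33.7 in EpiLC and Tbx3 at 1165 and 44.9, whereas Nanog was at 2969.5 and 2498.5. Against untreated EpiLC, Tfcp2l1 was higher by 1.95 and Klf2 by 1.39, and the naive list had a median of 0.13 (percentile 84.9). Formative genes had a median of -1.16, with Fgf5 going from 1258.5 to 39.4 and Otx2 at -4.12, and core genes a median of -1.53, with Utf1 at -5.08 and Tdgf1 at -4.20. Wnt targets had a median of 1.05 (percentile 100), with Sp5 at 3.45 and Nkd1 at 3.31. Cdx1 and Cdx2, caudal homeobox genes, went from 20.4 to 202 and from 32.0 to 260.5. The BMP target list had a median of 1.21 (percentile 99.98), with Id3 at 1.59 and Id1 at 1.34, but Id2 at -2.62. The trophoblast list had a median of 1.00, led by Cdx2, Krt8 (2.13) and Krt18 (1.99). In all, 581 genes were at least 2-fold higher and 330 lower, with totals of 1532 and 511 for constants of 4 and 64.

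Over both states 6 genes fell with CHIR and PD in the limma fit and 0 rose, with 3173 at an unadjusted p under 0.05. These, lower in both states, were Spry4 (log2 difference -4.01, SE 0.12, adjusted p = 0.00244), the kinase gene Pim2 (-3.03, SE 0.16, adjusted p = 0.018), Etv4 (-2.87, SE 0.19), Dusp4 (-2.84, SE 0.13), Tmem59l (-2.61, SE 0.18) and Dusp6 (-2.21, SE 0.13). Adjusted over the list alone, 15 of 19 ERK-dependent, 9 of 12 formative and 8 of 12 core genes fell, and 5 of 13 Wnt targets, 3 of 8 trophoblast genes (Krt7, Krt8 and Krt18), Tfcp2l1 (1.64, SE 0.26), Nanog (1.15, SE 0.42) and Cdkn1a (1.61, SE 0.17) rose, whereas Lef1 fell. With trend and robust moderation 53 genes passed, 28 of which rose and 25 of which fell, with a constant of 4 or 64 in place of 16 in the intensities 1 passed, and without moderation 0 passed.

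In EpiLC, 205 of the 392 genes at least 2-fold higher with CHIR were also at least 2-fold higher with CHIR and PD, among them Hoxb1 (5.54 and 3.23) and Ddit4 (2.85 and 2.87), and 140 of the 206 lower genes were also lower. Independent lists of these sizes would share 10.3 and 3.06 genes, and simulated arrays without any effect, set against the same untreated array, shared a mean of 34.3 and 33.1. In mESC, 18 of 41 higher and 27 of 34 lower genes were shared, where the same simulation gave means of 32.7 and 34.75. Part of the overlap in EpiLC, and part or all of that in mESC, may come from the untreated array that both comparisons use. The simulated lists were not matched in length or noise to those of each state, so these counts do not show how large that part is.

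The responses of the states overlapped in part. Across 22180 genes, which are not independent replicates, the CHIR differences in mESC and EpiLC had Pearson r = 0.297 and Spearman rho = 0.232, and 22 genes were at least 2-fold higher in both (0.72 expected from independent lists), including Mixl1, Cdx1, Sp5, Dkk1 and Hoxb1. For PD added to CHIR, r was 0.207 and rho 0.13, and 34 genes were at least 2-fold lower in both (1.18 expected), including Spry4, Dusp4, Etv4 and Utf1. For CHIR with PD against untreated, r was 0.351 and rho 0.238, with 55 genes higher and 70 lower in both. CHIR reached the 2-fold mark in 75 genes in mESC and 598 in EpiLC, a difference between states that could not be tested with 1 array per group. With a constant of 4 in place of 16 in the intensities these counts were 300 and 1013, and with one of 64 they were 27 and 343.

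Lists of general cell functions differed in their behaviour. The ribosomal protein list lay within random lists in all 7 single-array comparisons, with medians from -0.08 to 0.09, and Rpl5 had 0.41 (SE 0.10, adjusted p = 0.0701 in limma) between the states. The 2-cell-like list also stayed within them, with medians from -0.30 to -0.13, but stood apart over both states for CHIR (median -0.22, percentile 1.54) and for CHIR with PD (median -0.36, percentile 0.08). Of the 7 single-array comparisons, the cell cycle list stood apart in mESC with CHIR alone (median -0.12, percentile 1.09), although the cyclin gene Ccnd2 was at 2.13 in EpiLC with CHIR and at -2.16 in mESC when PD was added. Glycolysis genes stood apart when PD was added in EpiLC (median -0.30, percentile 0.06), where cholesterol synthesis genes had 0.29 (percentile 99.9), and these had -0.18 (percentile 0.24, 7 of 7 lower) in mESC with CHIR. The p53 target list stood apart in mESC with CHIR (median 0.19, percentile 99.6), with Cdkn1a at 1.07, and at -0.16 (percentile 1.27) when PD was added there. The amino acid and ER stress list had a median of -0.56 (percentile 0) when PD was added in EpiLC.

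**Figure D3:**
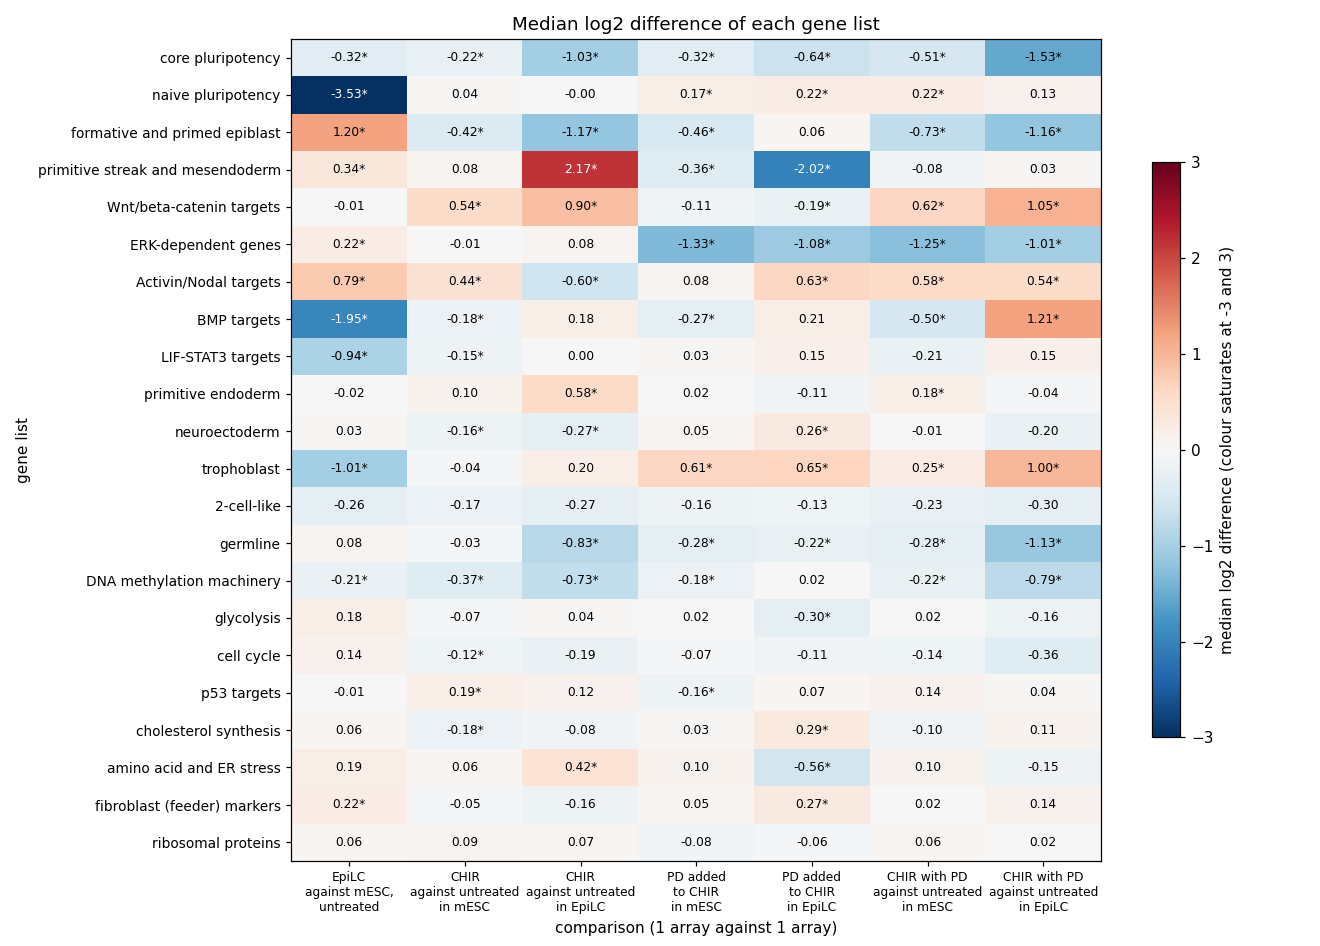
Median log2 difference of each of 22 gene lists (rows) in the 7 single-array comparisons (columns), with red for higher and blue for lower and an asterisk where the median stood apart from 10000 random lists. The streak and mesendoderm list reads 2.17 for CHIR in EpiLC and -2.02 when PD was added there.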

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

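The 2-fold threshold is that of the comparisons, but its use to pick genes that moved in opposite directions was chosen after the values had been seen, each value is from 1 array per group, and the differences between states were not tested.

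When PD was added to CHIR, 4 genes differed at least 2-fold in opposite directions in the 2 states, where independent lists would give 1.77. The BMP target Id3 was at -1.15 in mESC and 1.44 in EpiLC on the log2 scale. Has2, which encodes a hyaluronan synthase, was at -1.25 in mESC and went from 265 to 748 in EpiLC. Zfp423, which encodes a zinc finger protein, was at -1.35 and 1.38, and Slit2, which encodes a guidance cue, at 1.00 and -1.77.

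With CHIR and PD against untreated cells, 10 genes were lower in mESC and higher in EpiLC, where independent lists would give 6.96 opposite genes. Of these, 9 are named here and the other is a small RNA symbol, which the rule for named genes passes over. Id1 was at -1.89 and 1.34 and Id3 at -1.39 and 1.59. The cyclin gene Ccnd2 was at -1.72 and 2.09, Zfp36l1 at -1.65 and 1.27, Has2 at -1.46 and 1.22, Zfp423 at -2.14 and 1.01, Fgfbp1 at -1.10 and 2.88, Ndufa4l2 at -1.14 and 1.26, and Selenop at -1.11 and 1.11.

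Probes that carry several symbols were outside the comparisons. One shared by Sprr2a1, Sprr2a2 and Sprr2a3, genes for small proline-rich proteins of epithelia, went from 63.3 in untreated EpiLC to 2011 with CHIR (log2 difference 4.99). In mESC it went from 54.2 to 186 with CHIR. With CHIR and PD it was at 361.5 in EpiLC and 88.1 in mESC. A second probe, shared by these genes and Sprr2b, went from 845.2 to 22997.5 with CHIR in EpiLC, the highest intensity of that array. In EpiLC with CHIR and PD the second probe was at 4858.5. In mESC it was at 680.0 untreated, 2938.8 with CHIR and 900.9 with CHIR and PD. A probe shared by Rgma, which encodes a BMP co-receptor, and A730056A06Rik went from 82.8 in untreated EpiLC to 681.5 with CHIR and PD (log2 difference 3.04).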

How the results depend on the processing

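The constants of 4 and 64 in place of 16 were chosen after the values had been seen, the other alternatives beforehand. Of the counts and correlations 68 stayed within 1.5 times or within the bootstrap spread and 40 moved; of the values for lists 687 kept direction and side of the random lists, 38 came inside them and 0 reversed. The values for lists cover the 22 fixed lists and not the 8 further ones. Of the fixed lists said to stand apart in the text, fibroblast markers between the untreated states came inside with a constant of 64. The cell cycle list with CHIR in mESC and the p53 list with PD added in mESC came inside with unmatched random lists. The others that came inside concern the cholesterol, fibroblast, neuroectoderm, stress, Wnt, primitive endoderm, glycolysis, naive, DNA methylation, LIF-STAT3 and germline lists in other comparisons. Over the 3 treatments 1016 genes passed between the states with a constant of 4, 0 without moderation, and 945 to 1276 without 1 treatment's pair of arrays. The even split between the states (921 rose, 920 fell) became 1264 and 846 with each array centred on its median, and 1037 and 1223 with every probe as its own feature. Gbx2 (-0.28 over the 3 treatments, not past the threshold) reversed to 0.20 with the highest-mean probe and to 0.14 without the untreated pair, the range without 1 pair being -0.67 to 0.14. For PD added to CHIR over both states 1 gene passed with a constant of 64, 7 with trend and robust moderation and 0 without moderation. For CHIR with PD 1 passed with a constant of 4, 1 with 64, 53 with trend and robust moderation (28 rose, 25 fell) and 0 without moderation. With a constant of 4, genes at least 2-fold apart numbered 300 (CHIR in mESC), 1013 (CHIR in EpiLC, 556 higher and 457 lower), 425 (PD added in mESC), 894 (PD added in EpiLC), 681 (CHIR with PD in mESC) and 1532 (CHIR with PD in EpiLC). With a constant of 64 they numbered, in that order, 27 (11 higher, 16 lower), 343, 73, 255, 157 and 511, and 447 between the untreated states. At 1.5-fold they numbered 539, 1943, 862 (390 higher, 472 lower), 1370.0, 1547 and 2934, and 2139 between the untreated states. Correlations of the states across genes became 0.405 (CHIR), 0.32 (PD added) and 0.481 (CHIR with PD) with genes above the median level, 0.227, 0.149 and 0.262 with a constant of 4, and 0.355, 0.26 and 0.43 with one of 64. A smaller constant widens and a larger one narrows differences of dim genes by construction, and a lower fold threshold admits more genes; for the other changes the cause was not tested. Between 2.14% and 2.74% of probes lay within 1 of the lowest intensity. Leaving out a state would leave the treatment comparisons without a test, so this was not run.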

Other observations

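The 8 further lists were written after a first look at the values, and of the tests given here those of the splits, of array scaling, of cell state, of visceral endoderm and of a mislabelled array were chosen only after the result was seen.

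Caudal Hox and Cdx genes, which pattern the posterior embryo, were listed after Hoxb1, Hoxb2, Cdx1 and Cdx2 had been seen among the genes highest with CHIR, so the medians of this list are descriptions and no test. Of 12 measured, 4 were at least 2-fold higher with CHIR in each state (medians 0.13 in mESC and 0.20 in EpiLC), 2 of the 13 listed being on fixed lists. Hoxb1 went from 27.2 to 87.7 in mESC and from 43.0 to 2008 in EpiLC, and Hoxb2 from 34.4 to 1102 in EpiLC. When PD was added in mESC the list had a median of -0.36, and in EpiLC one of 0.01. Retinoic acid targets, 10 measured and 0 on fixed lists, had medians of 0.21 with CHIR and 0.28 with CHIR and PD in EpiLC (percentiles 99.6 and 99.9). In mESC they had medians of -0.13 with CHIR and -0.02 with CHIR and PD (percentiles 3.13 and 48.3) and did not stand apart. Dhrs3, which encodes a retinaldehyde reductase and was chosen after its values were seen, was at 66.3, 32.3 and 189 in EpiLC untreated, with CHIR and with CHIR and PD.

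Of 10 paraxial and presomitic mesoderm genes, a list that leaves out Msgn1 and Tbx6, 3 were at least 2-fold higher and 1 lower in EpiLC with CHIR (median 0.15, percentile 93.8), with 0 on fixed lists. That list stood apart for CHIR over both states (median 0.18, percentile 98.99) and for PD added in EpiLC (median -0.19, percentile 2.36). The 8 endothelial and blood genes, 1 on a fixed list, had a median of 0.02 (percentile 68.3), and the 9 anterior neural genes, 2 on fixed lists, had -0.06 (percentile 29.2), both in EpiLC with CHIR.

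Of the 10 splits of the 6 arrays into 3 and 3, 1, the real one, gave as many as 1841 genes between the states, and the highest of the others gave 0. Splits of 6 arrays are too few for a share under 0.05. The fits of the other splits had no term for cell state, which left that difference in their residual. Low counts there were therefore largely fixed in advance, and no conclusion is drawn from them.

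CHIR moved more genes at least 2-fold in EpiLC than in mESC. Genes in each of 20 groups of like level were shifted by the amount that leaves fewest EpiLC genes at least 2-fold apart. There were then 548, 7.3 times the 75 in mESC. With a constant of 4 in place of 16 in the intensities there were 946 and 300 (3.2 times). These counts argue against array scaling only in the form of a shift shared by genes of like level. Shifts leave the spread of the differences within a group as it is (SD over all genes 0.415 in EpiLC and 0.234 in mESC), so they cannot address a difference in gain between arrays. With quantile normalization again, which gives all arrays the same distribution, the counts were 584 in EpiLC and 80 in mESC. Measurement noise of single probes as the whole cause is argued against by second probes. Of these, 80% (12 of 15, exact interval 51.9 to 95.7%) went the way of the brightest probe, where such noise would give about 50%. The bound of more than 80% set beforehand was not exceeded, so probe noise as part of the cause stays open. Second probes read the same RNA on the same array, so they cannot address variation between single cultures, which was not tested. A response that depends on cell state may also account for the ratio of 8.0 (598 and 75 genes), and was not tested with 1 array per group. The states also differed in medium, with Activin A and bFGF for EpiLC and LIF and BMP4 for mESC. State and medium therefore cannot be told apart in these arrays.

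Mesoderm genes such as Msgn1 and Tbx6 were high on the EpiLC array with CHIR. Visceral endoderm cells in that culture would bring their abundant transcripts, but that list of 10 genes, 4 of them also on the primitive endoderm list, had a median of -0.13 (percentile 21.1) and no member above 0.45, with Ttr at 66.2 and 45.2 and Afp at 46.2 and 63.3 in untreated and CHIR-treated EpiLC. A mislabelled array is argued against by its Wnt targets, at a median of 0.90 above untreated EpiLC, together with ERK-dependent genes at 0.08. The visceral endoderm list does not show which cells carried Msgn1 and Tbx6, and no biological explanation for their levels was tested.

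Cxcl10 and Cxcl11, chemokine genes that interferon induces, were high on the EpiLC array with CHIR and PD. The other interferon-stimulated genes, 14 measured and 0 on fixed lists, had a median of -0.20 against CHIR alone (percentile 0.91), with 0 at least 2-fold higher. With CHIR alone, 3 of them were already at least 2-fold higher than in untreated EpiLC. Against untreated EpiLC the array with CHIR and PD had a median of -0.16 for these genes (percentile 18.1), with 1 at least 2-fold higher. These values argue against an interferon response across the list, not in single members. The 8 NF-kB targets, 0 on fixed lists, had a median of 0.23 (percentile 98.7) with 0 at least 2-fold higher, under the bound of 0.3 set beforehand against this explanation, but by less than the spread of random lists (-0.21 to 0.20), so NF-kB activity stays open. Against untreated EpiLC the list had a median of 0.49 on that array (percentile 99.8), with 8 of 8 higher and 2 at least 2-fold. That list also stood apart when PD was added in mESC (0.22, percentile 98.9) and with CHIR alone in EpiLC (0.37, percentile 99.7), where Cxcl10 was at 53.4 untreated and 57.5 with CHIR.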
